A study of Mus musculus with 24 samples.

How the data were processed

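Transcript levels were measured on Illumina mouse bead arrays in 24 samples, 3 wild-type and 3 Cirh1a heterozygote samples at each of 4 stages. Per the labels, the samples were whole embryos at embryonic day (E) 8.5 and E9.5 and liver at E11.5 and E12.5, taken from littermates of the C57BL/6 JAX strain into RNAlater. The heterozygotes carried a β-Geo gene trap in Cirh1a, and genotypes were read from yolk sac by PCR. Total RNA was purified on Qiagen columns, and biotinylated cRNA was made with the Ambion MessageAmp kit.

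The deposited values are log2 expression values per target ID (a transcript target on the array, read by 1 or more probes), normalized by the authors. The background correction, the normalization method and the software are not stated. From the values, the E8.5 and E12.5 arrays share 1 set of percentiles, with a largest gap of 0.00116 on the log2 scale, so these 12 arrays were normalized together. The E9.5 and E11.5 arrays each have their own distribution, with largest percentile gaps of 4.45 and 4.87 to the E8.5 arrays. The planned tests of E9.5 against E8.5 and of E12.5 against E11.5 were therefore not run, and every heterozygote effect was a difference within a stage. A further 4 tables hold 48 columns of unnormalized signal and detection p-values under names that match no sample label; their values were not used here, and only their probe identifiers were read, to count the probes of each target ID.

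The comparisons, the gene lists and most alternatives were fixed before the data were examined. That plan assumed unnormalized signal with detection p-values. Since no such column could be given to a sample, the planned background correction and normalization were replaced by the authors' log2 values, and the planned detection filter by a filter on level. Within a stage, a target ID was tested when its mean over the 6 arrays was above the median of all target IDs at that stage; this filter was set before the first fit. In the fits over all 24 arrays, a target ID needed values on all 24 arrays and a level above the median in at least 1 stage; this filter was set after the stage results had been seen. Of the 31483 target IDs, 13425 matched a gene symbol of the RefSeq annotation of the mouse genome, 8110 matched a synonym, and 9948 kept the name in the table.

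Each stage was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), heterozygote minus wild type, with two-sided p-values adjusted by the Benjamini-Hochberg method over the target IDs tested and a threshold of 0.05. A joint limma fit of the 24 arrays with 1 mean per stage and genotype gave the average effect over the 4 stages and the effect in liver minus that in whole embryo. It takes 1 spread per target ID for all stages. The median SE of the stage fits was 0.223 at E8.5, 0.0647 at E9.5, 0.0909 at E11.5 and 0.157 at E12.5. For a single stage taken from the joint fit, p-values can therefore be too small at E8.5. Cirh1a had no value at E11.5 analysed here, so its average was taken over 3 stages, with an exact two-sided permutation test within stages. At a single stage, 3 arrays against 3 cannot give an exact p under 0.1. The number of arrays limits the precision. Pearson correlations between the arrays of a stage ranged from 0.973 to 0.987 at E8.5, from 0.995 to 0.998 at E9.5, from 0.991 to 0.995 at E11.5 and from 0.987 to 0.992 at E12.5.

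The fit was tested on simulated data, in which 200 target IDs of the same level and spread were shifted. At E8.5 it recovered 0% of shifts of 0.5 log2, 19.5% of shifts of 1 and 75.0% of shifts of 2. The shares for a shift of 1 were 98.5% at E9.5, 91.0% at E11.5, 53.0% at E12.5 and 98.0% for the average effect. For a shift of 0.5 they were 80.0%, 32.5%, 0% and 75.5%. False calls numbered 0 to 14 per simulation. The simulated noise was normal and independent between target IDs, with 1 spread over all stages for the average effect. Recovery and false calls on the real arrays can therefore differ.

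Gene lists were tested with limma's camera at a preset correlation of 0.01, with the target ID of highest mean level for each gene, and adjusted over 29 lists at 4 stages (116 tests), or over the 29 lists for the average effect and for liver minus embryo. Camera with an estimated correlation and fry were alternatives. Fry asks only whether the genes of a list move, on balance, in 1 direction, and its mixed form whether they move in either. Counts of members were also adjusted over the list alone. The lists covered ribosome production (SSU processome, large ribosomal subunit biogenesis, cytosolic ribosomal proteins, RNA polymerase I and rRNA transcription), cell state (p53 targets, S phase, mitosis, NF-kappaB targets, hypoxia and glycolysis, unfolded protein and integrated stress response, immediate-early and heat shock genes, cholesterol synthesis, oxidative phosphorylation) and the liver (hepatoblast and hepatocyte genes, cholangiocyte and ductal plate genes, bile acid synthesis and transport). They also covered blood and vessels (definitive erythroid genes, embryonic globins, myeloid, megakaryocyte and endothelial genes), other tissues (mesenchyme, cardiac and striated muscle, neural, somite and tail bud, posterior Hox, visceral endoderm with placenta and decidua), the genes flanking Cirh1a on chromosome 8, and sex-linked genes.

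Named genes followed a fixed rule: Cirh1a, the target IDs past the threshold, and then those of smallest unadjusted p whose 3 heterozygote values all lay on one side of the 3 wild-type values, up to 10 in each direction. Not every gene under this rule is reported here. In the fits over 24 arrays the requirement was the same direction at all 4 stages, reversed between liver and embryo for the difference of the 2. For a list, the text gives members past the threshold adjusted over the list alone, or otherwise those with the largest moderated statistic. Genes outside this rule, such as those named to describe a fault of the E8.5 values or the levels by stage, were chosen after their values had been seen.

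The alternatives were another level filter or none, cyclic loess or median centring of the authors' values, 1 target ID per gene, the replicate number as a block, array weights, eBayes with trend and robust, the mean level of the Y-linked genes as a covariate (not in the fit of E8.5 alone, where it coincides with genotype), an adjusted p of 0.10, a fit of all 24 arrays for a stage, each array or stage left out in turn, and the other list tests. In the fits over several stages the covariate had 1 slope for all arrays, those of E8.5 included. Those on the level filter and on the rescaling of the authors' values were chosen after seeing the data. A test of E12.5 liver against E8.5 embryo was added after the files were seen, run, and then set aside, because many abundant transcripts read at background in the E8.5 arrays.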

Results

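The arrays covered 8 groups of 3 samples: wild-type and Cirh1a heterozygote whole embryos at E8.5 and at E9.5, and wild-type and Cirh1a heterozygote livers at E11.5 and at E12.5. Cirh1a encodes cirhin, a protein of the SSU processome, the complex that makes the small ribosomal subunit. Values were given for 31483 target IDs, of which 25206 had values on all 24 arrays and 6262 on the E9.5 and E11.5 arrays alone. The comparisons asked which transcripts differ between heterozygote and wild-type littermates at each stage, over the stages, and in liver against whole embryo.

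The E8.5 arrays lacked signal for a set of abundant transcripts. Of 3963 target IDs in the upper quintile of level at the 3 other stages, 198 lay below the median at E8.5, against 0 when E9.5, E11.5 or E12.5 was the stage in question. Rpl18, a protein of the large ribosomal subunit, had a log2 level of 1.73 ± 0.23 (SD, n = 6) at E8.5 and of 14.33 ± 0.03, 13.64 ± 0.05 and 12.96 ± 0.06 at E9.5, E11.5 and E12.5. The nucleolar protein Npm1 (2.50 ± 0.31), the tubulin Tubb5 (2.06 ± 0.39) and the intermediate filament Vim (1.70 ± 0.19) were as low at E8.5. Of the 198 target IDs, 185 (93.4%) had several probes, against 1742 of 3763 (46.3%) of those that stayed above the median. The E8.5 comparison included 0 of the 198, whereas the fits over 24 arrays included all 198.

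Cirh1a transcript in the heterozygotes was close to 50% of the wild-type level at the 3 stages with a value. It fell by 0.86 on the log2 scale at E9.5 (SE 0.0714, adjusted p = 0.00771), to 55.0% of wild type with a 95% interval of 49.2% to 61.5%. The log2 level there was 10.89 ± 0.14 (SD, n = 3) in heterozygotes and 11.75 ± 0.02 in wild type. The difference was -0.95 at E8.5 (SE 0.147, 51.8% of wild type, adjusted p = 0.802) and -0.92 at E12.5 (SE 0.122, 52.9%, adjusted p = 0.669), and the 3 heterozygote values lay below the 3 wild-type values at each of the 3 stages. Over E8.5, E9.5 and E12.5 together Cirh1a fell by 0.91 (SE 0.0654, adjusted p = 1.0e-05), to 53.2% of wild type (48.3% to 58.6%), with an exact permutation p of 0.00025. The exact p at each single stage was 0.1, the smallest that 3 arrays against 3 allow. The E9.5 call was lost without wild type replicate 1 (adjusted p = 0.0643), replicate 2 (0.0718) or replicate 3 (0.0815).

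**Figure D1:**
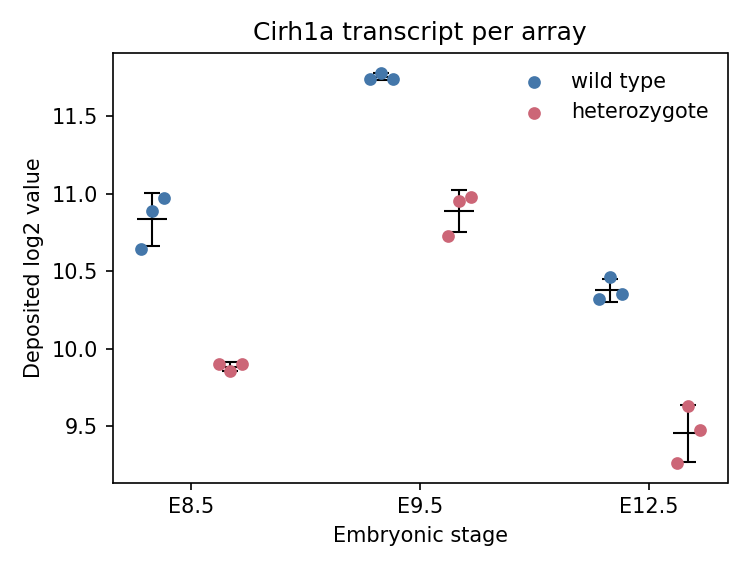
Deposited log2 level of Cirh1a at E8.5, E9.5 and E12.5; each point is an array (3 per group), and black bars are the mean ± SD. At each stage the 3 heterozygote values sit below the 3 wild-type values, by 0.95, 0.86 and 0.92 on average.

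At E8.5 the heterozygote and wild-type embryos differed in sex-linked transcripts. Xist, the noncoding RNA that silences an X chromosome in female cells, was at 9.64 ± 0.91 (SD, n = 3) in the heterozygotes and 2.14 ± 0.14 in wild type, a rise of 7.49 (SE 0.438, adjusted p = 0.00548). The Y-linked genes Eif2s3y, a subunit of a translation initiation factor, and Kdm5d, a histone demethylase, fell by 7.27 (SE 0.222) and by 5.22 (SE 0.172), both with an adjusted p of 0.000212. For these 3 genes the lower group read at background, so the differences are lower bounds. Ddx3y, another Y-linked gene, with 3 probes, read near background in both genotypes (2.26 ± 0.29 and 2.38 ± 0.35). The level of the Y-linked genes had a Pearson r of -0.998 with genotype across the 6 arrays, so any other difference at this stage is also a difference between arrays with and without Y-linked signal.

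These 3 were all the target IDs past the threshold of the 12603 tested at E8.5; 475 had an unadjusted p under 0.05, where 630 are expected by chance. In a fit of all 24 arrays the E8.5 count was 228, with Cirh1a called (adjusted p = 0.00177). That fit takes 1 spread per target ID for all stages. The median SE was 0.223 in the E8.5 fit and 0.0647 in the E9.5 fit, so the shared spread can be too small for E8.5. The groups did not overlap for 880 target IDs (6.98%), where chance gives 10%. The Xist call was lost without wild type replicate 1 (adjusted p = 0.0912), replicate 2 (0.0649), replicate 3 (0.0564) or heterozygote replicate 2 (0.0589). Among the other genes of smallest p were Cltrn, a membrane protein of amino acid transport (1.04, SE 0.158), Tor3a, a torsin ATPase (1.42, SE 0.218), and Atp2b4, a calcium pump (0.89, SE 0.160). On the negative side were Trim65, a ubiquitin ligase (-1.14, SE 0.178), Yod1, a deubiquitinase (-1.07, SE 0.192), and Mxd1, a Myc antagonist (-0.76, SE 0.143). Their adjusted p values were 0.802 to 0.922, and their log2 levels lay between 2.81 and 5.35.

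Of the gene lists, cholesterol synthesis was lower in the E8.5 heterozygotes, with 21 of its 25 tested members negative and a median change of -0.27 (adjusted p = 2.083e-05). The adjusted p was 0.852 with an estimated correlation. Hsd17b7, an enzyme of the late pathway, was the 1 member lower adjusted over the list alone (-0.90, SE 0.165), at a log2 level of 2.24 against 3.14, near background. Insig1, which holds the sterol sensor in the endoplasmic reticulum, had -0.92 (SE 0.286), the sterol demethylation enzyme Msmo1 -0.68 (SE 0.261) and the fatty acid desaturase Scd1 -0.47 (SE 0.164). Somite and tail bud genes were higher, with 18 of 24 members positive and a median of 0.20 (adjusted p = 0.0376, and adjusted p = 0.862 with an estimated correlation). Among them were the caudal transcription factor Cdx4 (0.40, SE 0.192), Nkx1-2 of the posterior growth zone (0.72, SE 0.297) and the activin antagonist Fst (0.49, SE 0.239). This call was lost without wild type replicate 1 (adjusted p = 0.310), wild type replicate 2 (0.176) or heterozygote replicate 1 (0.672). Heterozygote replicate 1 had an embryonic globin score of -4.08, against 0.09 to 1.21 in the other 5 arrays; the cause was not tested. Embryonic globins had a median of -1.14 (adjusted p = 0.298), posterior Hox genes -0.23 (0.158), endothelial genes -0.14 (0.0881), mesenchyme genes -0.10 (0.159) and visceral endoderm genes 0.28 (0.161). The sex-linked list passed with an adjusted p of 0.00113 (0.852 as the adjusted p with an estimated correlation); its median was -5.22 over 3 genes, of which Xist rose and the other 2 fell.

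**Figure D2:**
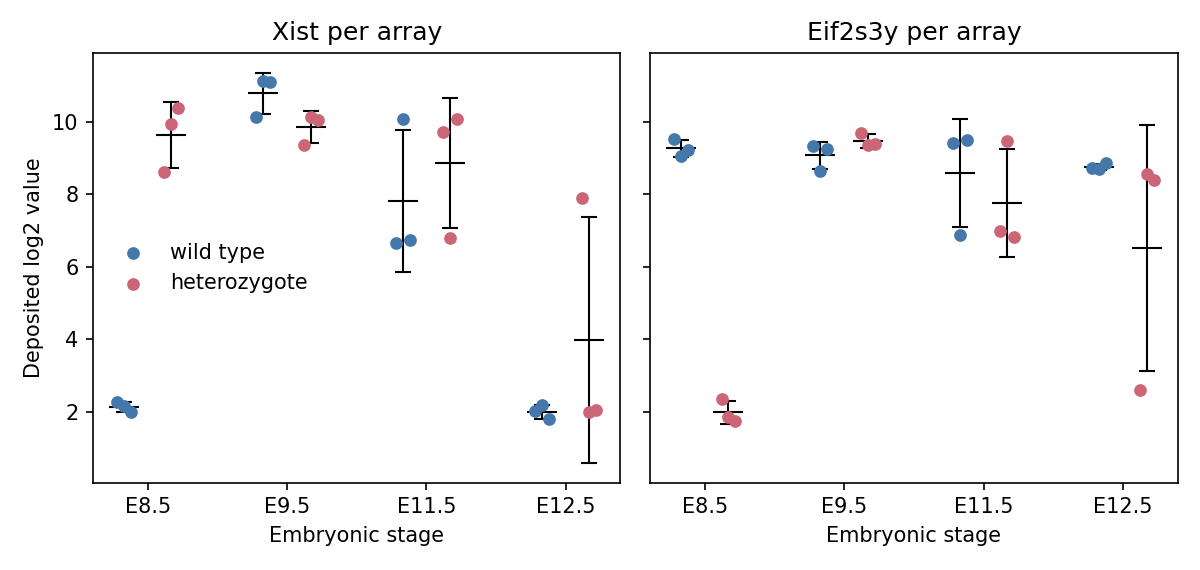
Deposited log2 levels of Xist (left) and Eif2s3y (right) per array (points, 3 per group) at the 4 stages, with mean ± SD as black bars. At E8.5 all heterozygote arrays carry Xist and all wild-type arrays carry Eif2s3y, at E9.5 every array carries both, and at E12.5 only heterozygote replicate 1 carries Xist (7.90).

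At E9.5 the lists of liver and of extraembryonic genes were called higher in the heterozygote embryos, and those of neural and of megakaryocyte genes lower, calls that are each lost with an estimated correlation (adjusted p = 0.852). The hepatocyte score was 0.47, 0.15 and -0.04 in heterozygote replicates 1, 2 and 3. Of 29 tested hepatoblast and hepatocyte genes, 23 were positive, with a median change of 0.29 (adjusted p = 1.5e-08), and 15 were higher adjusted over the list alone. The adjusted p was 0.852 with an estimated correlation. The 15 included the lipoprotein components Apoa1 (1.29, SE 0.252) and Apom (1.11, SE 0.213), the thyroxine and retinol carriers Ttr (0.96, SE 0.207) and Rbp4 (0.94, SE 0.201), and fibrinogen Fga (0.85, SE 0.184). Of 24 genes of visceral endoderm, placenta and decidua, 7 were higher and 1 lower adjusted over the list alone, with a median of 0.11 (adjusted p = 0.00238, and adjusted p = 0.852 with an estimated correlation). Amn, a part of the endocytic receptor of the visceral endoderm, had 1.17 (SE 0.241), Apoa4 0.85 (SE 0.162) and the homeobox gene Rhox5 0.74 (SE 0.168), whereas the endocytic receptor Lrp2 had -0.25 (SE 0.0649).

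Neural and neural crest genes fell as a list at E9.5, with 23 of 31 members negative, a median of -0.09 (adjusted p = 1.7e-05, and adjusted p = 0.852 with an estimated correlation) and 10 lower adjusted over the list alone. The neuronal RNA-binding protein Elavl3 had -0.48 (SE 0.0648), the neural progenitor filament Nes -0.48 (SE 0.0748), the neurogenic factor Neurod4 -0.51 (SE 0.0973) and the microtubule protein Dcx of young neurons -0.31 (SE 0.0510). Megakaryocyte genes fell with a median of -0.18 over 12 members (adjusted p = 0.000735, and adjusted p = 0.852 with an estimated correlation), 5 of them adjusted over the list alone, such as platelet factor 4 (Pf4, -0.79, SE 0.214) and the platelet glycoprotein Gp5 (-0.37, SE 0.0763).

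Endothelial genes were higher at E9.5 (26 members, median 0.07, adjusted p = 0.00230), with 5 past the threshold adjusted over the list alone, including Etv2, a factor that starts the blood and vessel lineage (0.37, SE 0.0586), and Lyve1, a hyaluronan receptor of sinusoidal and lymphatic vessels (0.64, SE 0.178). The adjusted p was 0.852 with an estimated correlation. Cardiac and striated muscle genes were higher (30 members, median 0.11, adjusted p = 0.000388, and adjusted p = 0.862 with an estimated correlation), with 5 higher adjusted over the list alone, such as troponin I (Tnni3, 0.33, SE 0.101), and 1 lower, the calcium pump regulator Pln (-0.34, SE 0.0777). Hypoxia and glycolysis genes were higher in 27 of 31 members (median 0.12, adjusted p = 0.000802, and adjusted p = 0.862 with an estimated correlation), with 0 adjusted over the list alone and 2 at an unadjusted limma p under 0.05. The glucose transporter Slc2a3 had 0.28 (SE 0.0973). Without heterozygote replicate 1 the cardiac list had an adjusted p of 0.123 and the hypoxia list one of 0.526, and the hypoxia list had 0.0915 without wild type replicate 2.

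The SSU processome, to which Cirh1a belongs, did not pass the test at E9.5: of 45 members, Cirh1a was the only one past the threshold, and the list had an adjusted p of 0.868. The p53 target list also did not pass (35 members, median 0.03, adjusted p = 0.0881, and 0.852 with an estimated correlation). Adjusted over the list alone, 4 of its members were higher and 2 lower. Cyclin G1 (Ccng1, 0.42, SE 0.0513), the cell cycle inhibitor Cdkn1a (0.27, SE 0.0632) and the Akt inhibitor Phlda3 (0.26, SE 0.0635) were higher, and the receptor Notch1 (-0.39, SE 0.0831) was lower.

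Past the threshold over all 15741 target IDs at E9.5 there were 0 higher and 1 lower, Cirh1a, and 15 at an adjusted p under 0.10. Unadjusted limma p values under 0.05 numbered 1742, where 787 are expected, and the groups did not overlap for 2770 target IDs (17.6%), where chance gives 10%. Next in order were Phlda2, an imprinted gene that restrains placental growth (0.65, SE 0.0743), and Ccng1, with Megf10, a receptor for engulfment (-0.49, SE 0.0595), and Myt1, a zinc finger factor of neural progenitors (-0.43, SE 0.0544), all at an adjusted p of 0.0543. Inmt, a methyltransferase (-0.53, SE 0.0697), the teneurin Tenm4 (-0.43, SE 0.0559), Elavl3 and the long noncoding RNA Crnde (-0.48, SE 0.0652) had 0.0571. Higher in all 3 heterozygote arrays, at adjusted p values of 0.112 to 0.146, were also Etv2, the left-right signal Gdf1 (0.35, SE 0.0590) and the iron-sulfur cluster protein Ciapin1 (0.34, SE 0.0592). So were the proteasome subunit Psmb10 (0.30, SE 0.0537), the sodium pump regulator Fxyd2 (0.57, SE 0.101) and the urea cycle enzyme Ass1 (0.41, SE 0.0763).

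Every E9.5 array carried Xist and Y-linked transcripts together. At the other stages the arrays with Xist had Eif2s3y near background, though E12.5 heterozygote replicate 1 had Ddx3y at 5.12. The labels do not say whether a sample was 1 embryo or a pool; if pools, the n of 3 counts pools and the small spread at E9.5 is one between pools. Xist was at 9.84 ± 0.44 (SD, n = 3) in heterozygotes and 10.78 ± 0.57 in wild type, and Ddx3y at 8.71 ± 0.13 and 8.31 ± 0.29. Adjusted over the list alone, 3 sex-linked genes were higher and 1 lower, while the list had an adjusted p of 0.159. With the Y-linked level as a covariate, Cirh1a had -0.80 (adjusted p = 0.0813) and the count was 0. The count was 54 without heterozygote replicate 3, whose hepatocyte list score of -0.04 lay below those of heterozygote replicates 1 (0.47) and 2 (0.15), and 0 without any single wild-type array.

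**Figure D3:**
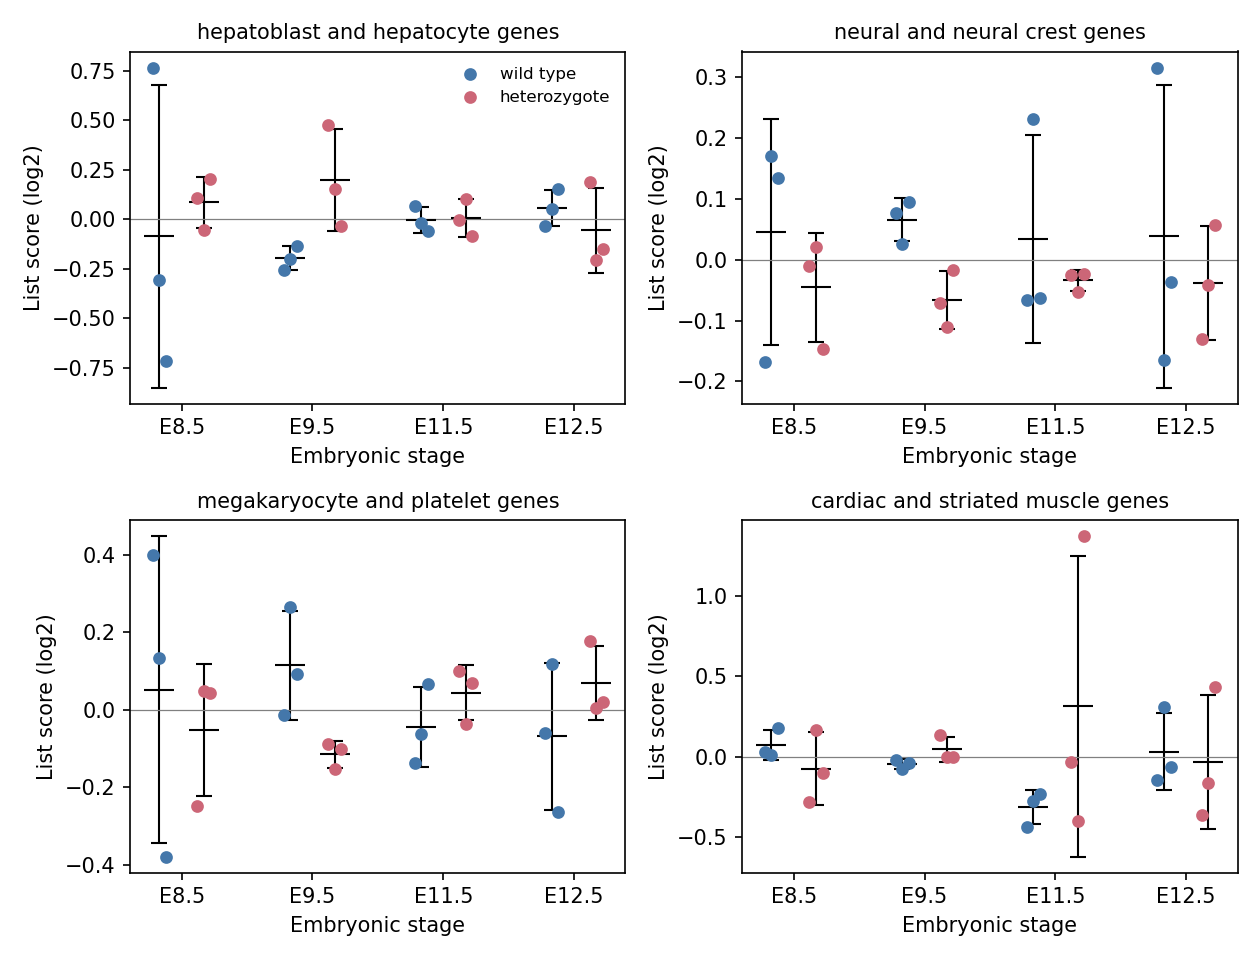
Scores of 4 gene lists per array (points, 3 per group), the mean log2 difference of the list's genes from their mean at that stage, with mean ± SD as black bars and a grey line at 0. At E9.5 the mean hepatocyte score is higher and the mean neural and megakaryocyte scores lower in heterozygotes. These list calls are lost with an estimated correlation (adjusted p = 0.852). At E11.5 heterozygote replicate 3 stands apart in cardiac genes (1.37).

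In E11.5 liver, mitochondrial and cardiac gene lists were called higher and cholesterol and erythroid lists lower in the heterozygotes. Each of these calls is lost with an estimated correlation (adjusted p = 0.852 or 0.862). Of 75 genes of oxidative phosphorylation, 63 were positive, with a median of 0.14 (adjusted p = 1.7e-08), such as the complex I subunit Ndufb9 (0.29, SE 0.0910) and Cox7b of cytochrome oxidase (0.41, SE 0.159). The adjusted p was 0.862 with an estimated correlation and 0.271 without wild type replicate 1. All 17 cardiac and striated muscle genes were positive, with a median of 0.58 (adjusted p = 3.6e-07, and adjusted p = 0.862 with an estimated correlation), such as atrial myosin light chain Myl7 (1.45, SE 0.701). The list score of heterozygote replicate 3 was 1.37, and those of the other heterozygotes were -0.03 and -0.40; without that array the adjusted p was 0.0837. Cholesterol synthesis was lower (24 of 28 negative, median -0.09, adjusted p = 0.000802, adjusted p = 0.852 with an estimated correlation, and 0.0843 without heterozygote replicate 3), with Scd1 at -0.49 (SE 0.102), past the threshold adjusted over the list alone, and the pathway enzyme Hmgcs1 at -0.23 (SE 0.0936).

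Megakaryocyte genes were higher in the E11.5 heterozygote livers (19 members, median 0.10, adjusted p = 0.00655), with the integrin Itga2b at 0.19 (SE 0.0798), and erythroid genes lower (38 members, 30 negative, median -0.07, adjusted p = 0.0483), with spectrin Sptb at -0.15 (SE 0.0859). With an estimated correlation the adjusted p was 0.862 for both lists. The megakaryocyte list had an adjusted p of 0.259 without wild type replicate 1, 0.166 without heterozygote replicate 1 and 0.104 without heterozygote replicate 3. The erythroid list had 0.718 without wild type replicate 1, 0.913 without wild type replicate 3 and 0.784 without heterozygote replicate 3. By limma, 0 of 15734 target IDs passed the threshold and 414 had an unadjusted p under 0.05, where 787 are expected. The groups did not overlap for 1288 (8.19%), where chance gives 10%. Among the genes of smallest p were Ciapin1 (0.52, SE 0.0807), Scd1, the tRNA-modifying Trmt12 (-0.46, SE 0.0971), the immediate-early factor Egr1 (-0.38, SE 0.0890), the cysteine dioxygenase Cdo1 (0.30, SE 0.0725) and the muscle precursor factor Msc (-1.17, SE 0.306), each with an adjusted p of 1.00. Wild-type replicate 2 and heterozygote replicates 1 and 3 carried Xist (10.06, 9.71 and 10.06), and the remaining E11.5 arrays carried Y-linked transcripts.

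In E12.5 liver, genes of hypoxia and glycolysis were higher in the heterozygotes in 22 of 28 members, with a median of 0.11 (adjusted p = 0.00554, and adjusted p = 0.852 with an estimated correlation). Examples are hexokinase Hk1 (0.32, SE 0.114) and the oxygen-dependent hydroxylase Egln3 (0.35, SE 0.144). Megakaryocyte genes (17 members, median 0.13, adjusted p = 0.0208), endothelial genes (24 members, median 0.11, adjusted p = 0.0208), large ribosomal subunit biogenesis (44 members, median 0.06, adjusted p = 0.0483) and embryonic globins (3 members, median 0.31, adjusted p = 0.0483) were higher, and hepatocyte genes lower (30 of 43 negative, median -0.08, adjusted p = 0.0382). The adjusted p of these 5 lists was 0.862 with an estimated correlation. Among their members, the blood and vessel factor Fli1 had 0.69 (SE 0.230), the endothelial nitric oxide synthase Nos3 0.33 (SE 0.135), the large subunit maturation factor Eif6 0.54 (SE 0.200), the globin Hbb-bh1 0.31 (SE 0.146) and prothrombin (F2) -0.21 (SE 0.112).

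Each of the 6 E12.5 lists lost its call without some single array. Without heterozygote replicate 2 the adjusted p was 0.175 for hypoxia, 0.434 for endothelial genes, 0.575 for large subunit biogenesis, 0.258 for globins and 0.762 for hepatocyte genes. The megakaryocyte list had 0.373 without heterozygote replicate 1 and 0.540 without wild type replicate 3. Without wild type replicate 1 the values were 0.0623 (megakaryocyte), 0.0506 (endothelial), 0.155 (large subunit) and 0.107 (globins), and without wild type replicate 2 they were 0.0688 (hypoxia), 0.0920 (endothelial and large subunit), 0.0958 (globins) and 0.112 (hepatocyte). Without wild type replicate 3 they were 0.0616 (endothelial), 0.121 (large subunit), 0.161 (globins) and 0.427 (hepatocyte), and without heterozygote replicate 3 they were 0.0751, 0.0820, 0.165 and 0.333 for the same 4 lists.

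By limma, 0 of 12603 target IDs passed the threshold at E12.5 and 486 had an unadjusted p under 0.05, where 630 are expected. The count was 31 in a fit of all 24 arrays, Cirh1a among them (adjusted p = 0.00688), and 1 with trend and robust eBayes. The groups did not overlap for 898 (7.13%), where chance gives 10%. Among the genes of smallest p besides Cirh1a were several with log2 levels of 2 to 5, such as Tcp11, a testis gene (0.92, SE 0.101), the replication checkpoint protein Topbp1 (1.05, SE 0.177), the ephrin receptor Epha4 (-0.93, SE 0.138), the phospholipase Plcb4 (-0.81, SE 0.110) and the nuclear receptor Nr0b1 (-0.68, SE 0.0974), with adjusted p values of 0.669 to 0.737. Xist was carried by heterozygote replicate 1 alone (7.90), which was also the only E12.5 array with Eif2s3y at background (2.62). Its Ddx3y level was 5.12, against 8.58 to 8.87 in wild type.

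Averaged over the 4 stages, the lists of cholesterol synthesis and neural genes were called lower in the heterozygotes, and those of hypoxia, mitochondrial, visceral endoderm and large ribosomal subunit genes higher. All 6 calls are lost with an estimated correlation (smallest adjusted p = 0.383). Cholesterol synthesis had 23 of 26 members negative and a median of -0.07 (adjusted p = 0.000485, and adjusted p = 0.383 with an estimated correlation), with 2 lower adjusted over the list alone, Hsd17b7 (-0.25, SE 0.0504) and Scd1 (-0.25, SE 0.0673). Neural genes had 28 of 37 negative and a median of -0.05 (adjusted p = 0.00745, and 0.383 with an estimated correlation), with Elavl3 at -0.27 (SE 0.0826). Hypoxia and glycolysis had 26 of 29 positive and a median of 0.07, with Hk1 at 0.27 (SE 0.0806), and oxidative phosphorylation had 60 of 69 positive and a median of 0.04; both had an adjusted p of 0.000801, which became 0.525 and 0.573 with an estimated correlation. The visceral endoderm, placental and decidual list had a median of 0.12 over 20 members (adjusted p = 0.0144) and large subunit biogenesis one of 0.02 over 44 (adjusted p = 0.0260), both at an adjusted p of 0.525 with an estimated correlation.

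Single stages and arrays decided most of these averages. Without E8.5 the cholesterol list had an adjusted p of 0.565, and without E9.5 the neural and the visceral endoderm lists had 0.155 and the hypoxia list 0.101. Without E11.5 the mitochondrial list had 0.349 and the visceral endoderm list 0.0661, and without E12.5 the hypoxia list had 0.0524. The neural list also had 0.0518 without E8.5 heterozygote replicate 3 and 0.0684 without E12.5 wild type replicate 1, and the mitochondrial list 0.134 without E11.5 wild type replicate 1. The visceral endoderm list had 0.0801 without E8.5 wild type replicate 2, 0.0680 without E8.5 wild type replicate 3, 0.158 without E8.5 heterozygote replicate 3 and 0.109 without E12.5 heterozygote replicate 1. The large subunit list had 0.0518 to 0.136 without any 1 of 9 arrays: E8.5 wild type replicates 1 and 2 and heterozygote replicate 3, E9.5 wild type replicate 3, E11.5 wild type replicate 2 and heterozygote replicates 2 and 3, and E12.5 wild type replicate 1 and heterozygote replicate 2. It had 0.0906, 0.0661 and 0.233 without E9.5, E11.5 or E12.5.

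By limma, 0 of 16402 target IDs passed the threshold for the average effect and 879 had an unadjusted p under 0.05, where 820 are expected. Without E8.5 wild type replicate 1 the count was 51, and it was 1 to 4 without E8.5 heterozygote replicate 2 or 3, E11.5 wild type replicate 2 or E12.5 heterozygote replicate 1 or 2. Ciapin1 had the smallest p, at 0.38 (SE 0.0696, adjusted p = 0.188), with differences of 0.36, 0.34, 0.52 and 0.31 at E8.5, E9.5, E11.5 and E12.5. Fli1 had 0.39 (SE 0.0861), the NF-kappaB inhibitor Nfkbib 0.30 (SE 0.0702), the endocytic adaptor Epn1 -0.29 (SE 0.0658) and the mitochondrial deformylase Pdf, a neighbour of Cirh1a on its chromosome, -0.25 (SE 0.0649), with adjusted p values of 0.364 to 0.548. In the same order of stages Fli1 had 0.73, 0.05, 0.08 and 0.69, and Nfkbib 0.65, 0.09, 0.09 and 0.39. Epn1 had -0.73, -0.07, -0.12 and -0.25, and Pdf -0.28, -0.19, -0.11 and -0.42. Each was largest in size at E8.5 and E12.5, where array medians were 2.70, against 6.63 at E9.5 and 6.91 at E11.5. Changes on such unlike scales need not be of like size, and at E8.5 sex and genotype coincide.

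Of the lists on ribosome production, the SSU processome had an average median of 0.03 (adjusted p = 0.137), cytosolic ribosomal proteins 0.01 (0.271) and RNA polymerase I and rRNA transcription 0.01 (0.561). Mitosis had a median of -0.03 (adjusted p = 0.105), NF-kappaB targets 0.02 (0.198), the unfolded protein and integrated stress response 0.03 (0.210), and p53 targets, S phase and immediate-early genes had an adjusted p of 0.839 each; for the first 2 of these the median was below 0 and the mean and the test above it, and for immediate-early genes the median was 0.01 while the test pointed down. Cholangiocyte genes had a median of -0.04 (adjusted p = 0.160), bile acid synthesis and transport -0.05 (0.137), myeloid genes 0.01 (0.793), mesenchyme genes -0.04 (0.316), posterior Hox genes -0.03 (0.555) and the genes flanking Cirh1a -0.02 (0.271). None of these lists passed the threshold at a single stage; their smallest adjusted p values were 0.0568 for cytosolic ribosomal proteins at E11.5 and 0.0689 for cholangiocyte genes at E9.5.

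The effect of heterozygosity was called different between liver and whole embryo for 1 target ID and 2 gene lists. The embryo side includes E8.5, where the level of the Y-linked genes had an r of -0.998 with genotype. A difference of sex at E8.5 can therefore enter these results. The stages were also on unlike scales, with array medians of 2.70 at E8.5 and E12.5, 6.63 at E9.5 and 6.91 at E11.5. Hepatocyte genes had a lower effect in liver than in embryo (44 members, 35 negative, median difference -0.21, adjusted p = 0.00545, and adjusted p = 0.697 with an estimated correlation), with Ttr at -0.60 (SE 0.257) and the methionine enzyme Mat1a at -0.99 (SE 0.288). Megakaryocyte genes had a higher effect in liver (17 members, 12 positive, median 0.19, adjusted p = 0.000761, and adjusted p = 0.697 with an estimated correlation), with 3 higher adjusted over the list alone, Gp5 (0.59, SE 0.117), the platelet kinase substrate Plek (0.70, SE 0.210) and Pf4 (0.73, SE 0.231). The hepatocyte list had an adjusted p of 0.0943 without E8.5 wild type replicate 2, 0.189 without E8.5 wild type replicate 3 and 0.0872 without E12.5 heterozygote replicate 2.

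Tmem267, which encodes a membrane protein, was the target ID past the threshold of 16402, with a difference of 1.30 (SE 0.196, adjusted p = 0.0364) and changes of -0.96, -0.39, 0.05 and 1.20 at E8.5, E9.5, E11.5 and E12.5. Its adjusted p was 0.0602 after cyclic loess, 0.0821 with the replicate block, 0.127 with array weights, and 0.0501 to 0.126 without any 1 of 13 arrays, namely all 6 from E11.5, E9.5 wild type replicates 1, 2 and 3 and heterozygote replicates 1 and 3, and E12.5 wild type replicate 2 and heterozygote replicate 3. Unadjusted p values under 0.05 numbered 798, where 820 are expected. Without E8.5 wild type replicate 1 the count was 68. It was 2 to 5 without any other E8.5 array, without E12.5 wild type replicate 1 or without E12.5 heterozygote replicate 1 or 2.

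Heterozygote effects of different stages were compared by Pearson correlation across genes, which are not independent replicates, in 6 pairs of stages. The largest r values were 0.183 between E8.5 and E9.5 (permutation p = 0.15, adjusted 0.45) and 0.132 between E9.5 and E11.5 (permutation p = 0.06, adjusted 0.36). The r was 0.0788 for E8.5 and E11.5, -0.00467 for E8.5 and E12.5, -0.0442 for E9.5 and E12.5 and 0.0233 for E11.5 and E12.5. No pair exceeded what other splits of the same arrays gave.

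Levels of different stages were set side by side without a test, since E9.5 and E11.5 were each normalized apart and the E8.5 values lack many abundant transcripts. The array medians were 2.70 at E8.5 and E12.5, 6.63 at E9.5 and 6.91 at E11.5. The fetal liver protein Afp was at a log2 level of 9.57, 9.73, 12.82 and 12.70 (means of 6 arrays) at E8.5, E9.5, E11.5 and E12.5, and the adult globin Hbb-b1 at 10.59, 11.20, 14.79 and 14.96. The neural factor Sox2 was at 5.50, 9.33, 6.81 and 2.58, and the tail bud factor T at 8.94, 9.71, 6.84 and 2.40; both lay below the array median at E11.5 and at E12.5.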

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

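The tests of an effect of heterozygosity itself on the sex-linked genes, of yolk sac tissue, of dilution and of the chromosome window were chosen after the results they concern had been seen. The other tests of this part were set before their results were seen. In this part, the SE of a median, or of a difference of medians, comes from resampling genes and not arrays. It does not measure the spread between samples.

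Tmem267 differed in its heterozygote effect between liver and embryo by 1.30 (SE 0.196), a call lost with cyclic loess (adjusted p = 0.0602), the replicate block (0.0821), array weights (0.127) or without any 1 of 13 arrays (up to 0.126). The hepatocyte list differed by a median of -0.21, a call lost with an estimated correlation (adjusted p = 0.697) and without E8.5 wild type replicate 2 or 3 or E12.5 heterozygote replicate 2 (adjusted p up to 0.189). The megakaryocyte list differed by a median of 0.19, a call lost with an estimated correlation (adjusted p = 0.697). For the count of target IDs in this comparison chance cannot be excluded: 46 of 100 splits of the arrays within stages gave at least the real count of 1. The highest other count, 29, may reflect a structure of the samples, which was not tested.

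At E8.5 the 3 wild-type arrays carried Y-linked transcripts without Xist, and the 3 heterozygote arrays carried Xist without Y-linked transcripts. Male wild-type and female heterozygote embryos fit this: X-linked genes that escape silencing had a median change of 0.264 (SE 0.257), taken from a fit without the level filter because 1 of the 4 genes lay below it, with Kdm6a at 0.65, Eif2s3x at 0.48, Ddx3x at 0.05 and Kdm5c at -0.30. The median is within 2 SE of 0, so this test is weak evidence beside Xist and the Y-linked genes themselves. Heterozygosity did not lower Eif2s3y at every stage, since 3 heterozygote liver arrays had it within 1 log2 unit of the highest wild-type array. The heterozygote embryos of E9.5 had it at 9.47 ± 0.18 (SD, n = 3). The 3 liver arrays, E11.5 heterozygote replicate 2 and E12.5 heterozygote replicates 2 and 3, had Xist at 6.79, 2.00 and 2.06. Their Kdm5d levels were 8.264, 5.435 and 5.067. Conversely, E11.5 wild type replicate 2 carried Xist (10.06) with Eif2s3y at 6.87. In liver these values argue against an effect of heterozygosity on Xist and Kdm5d as well. An effect limited to E8.5 is not excluded by them. The E8.5 lists may reflect sex as well as genotype, which these arrays cannot separate. A difference in age or tissue stays open, since heterozygote replicate 1 had an embryonic globin score of -4.08 against 0.09 to 1.21 in the other 5 arrays. For age, the E8.5 change had a Spearman rho of -0.0126 with the level difference E9.5 minus E8.5 over 10523 genes. That rho was not compared with other splits of the arrays, and tissue was not tested.

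At E9.5 the neural list was called lower and the liver and visceral endoderm lists higher in the heterozygotes, calls that are each lost with an estimated correlation (adjusted p = 0.852). More yolk sac tissue in the heterozygote samples could raise genes such as Amn and Apoa1. The median change of the whole visceral endoderm, placental and decidual list was 0.108 (SE 0.0994). This cannot tell, since the list also holds placental and decidual genes and its median does not measure yolk sac tissue alone. Its members among the most abundant genes of this and the hepatocyte list were Slc13a4 (0.85), Rhox5 (0.74) and Plac8 (0.09). Of its 41 genes on the array, 24 passed the level filter in the embryos, and 4 of these are on other lists too. A first form of this test used 6 genes picked for their change and was replaced after its result was seen. Dilution of embryonic RNA by such tissue stays open for the lower genes: the somite and tail bud list lay above the neural list by 0.138 (SE 0.06), but the mesenchyme and posterior Hox lists, added after the first result was seen, lay above it by only 0.0369 (SE 0.0442) and 0.0764 (SE 0.0555). Younger heterozygote embryos fit what was set in advance and stay open. The change had a Spearman rho of -0.128 with the level difference E9.5 minus E8.5 over 10523 genes (0.11 in absolute value for the highest other split). The 10 splits are too few for a share under 0.05, and E8.5 and E9.5 were normalized apart, which affects the level difference. Ttr (13.64 and 12.48), Apoa1 (12.59 and 10.95) and Hnf4a (8.69 and 7.80) were lower at E9.5 than at E8.5, while Afp was not (9.57 and 9.73). A larger share of tissue with such transcripts could also give a negative rho, so this test cannot separate age from tissue share. Different shares of male and female embryos would, by the rule set in advance, bring the neural change to 0 or above with the Y-linked covariate. The change stayed below 0, with a mean of -0.163 (SE 0.0472) with the covariate and -0.132 (SE 0.0341) without it. This cause cannot be excluded, since the covariate had an r of 0.684 with genotype over only 6 arrays.

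Pdf was lower and Ciapin1 higher at all 4 stages, with averages of -0.25 and 0.38 that did not pass the threshold. The same direction at all 4 stages was a condition of naming them, and 2389 of 16402 target IDs (14.6%) met it. Pdf and Ciapin1 lie on the chromosome of Cirh1a, with 2 tested genes between Cirh1a and Pdf and 67 between Cirh1a and Ciapin1. Sequence of another strain carried along with the gene trap could change neighbours, but the window of 100 tested genes on each side held 11 genes at p under 0.05, against a median of 10 and a highest count of 19 over 8482 windows, the 54.8th percentile. Crnde, Psmb10 and Fa2h also lie in this window, Crnde and Psmb10 being among the E9.5 genes of smallest p. For changes in either direction, mixed fry gave the genes flanking Cirh1a an unadjusted p of 6.3e-07 at E9.5. That test does not compare a list with other genes, and it was also low for p53 targets (3.7e-05), endothelial genes (9.9e-05) and mitosis (0.00011). Of 58 flanking genes, 2 were higher and 4 lower at an unadjusted limma p under 0.05, against 1742 of all 15741 target IDs. The mixed fry p of the flanking list was 0.627 at E8.5 and 0.658 at E11.5. The window count cannot tell, and a local effect of the trap itself on Pdf was not tested.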

How the results depend on the processing

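Of the counts, Cirh1a changes and correlations, 149 stayed close to their value under the other alternatives, 41 moved, 4 became stronger and 1 weaker; with 1 array left out 196 stayed close, 53 moved and 3 became weaker. A count that stayed close can still hold other target IDs, as at E8.5, where it was 2 without Xist. No called value changed sign; 4 of the 6 correlations, none of them called, took both signs with 1 array left out. The cause of the changes below was not tested. The values below are counts of target IDs past the threshold, numbers of gene lists past it, and log2 changes of Cirh1a.

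Without a level filter 1 list passed at E8.5 and 2 at E12.5. With the filter at the 65th percentile 9 target IDs passed at E9.5 and 10 lists for liver minus embryo. With target IDs above the median in all 4 stages 10 lists passed for the average and 5 for liver minus embryo. After cyclic loess of the authors' values 0 target IDs passed for liver minus embryo. These alternatives, and median centring, were chosen after seeing the data. The level filter removes transcripts near background, so changes of transcripts at low level were not tested.

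With the replicate number as a block 2 target IDs passed at E9.5, 0 for liver minus embryo, and 3 lists at E12.5. Pairing by number is not stated in the labels, and arrays of the same number shared no clear deviation (r of 0.177, 0.134 and 0.0971 at E8.5, and -0.393, -0.309 and -0.126 at E11.5). The Xist call at E8.5 was lost with the block (adjusted p = 0.140). With array weights 5 lists passed at E8.5, 9 target IDs at E9.5 and 0 for liver minus embryo.

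With trend and robust eBayes 18 target IDs passed at E9.5 and 1 at E12.5, and Cirh1a passed at E8.5 (-0.95, adjusted p = 0.00843) and E12.5 (-0.92, adjusted p = 0.0346). In a fit of all 24 arrays 228 target IDs passed at E8.5 and 31 at E12.5, Cirh1a passed at both (-0.95, adjusted p = 0.00177, and -0.92, adjusted p = 0.00688), and 1 list passed at E8.5 and 2 at E12.5. That fit shares 1 spread per target ID over stages of unequal spread. With the Y-linked covariate 0 target IDs passed at E9.5, where Cirh1a had -0.80 (adjusted p = 0.0813), 1 for the average and 3 for liver minus embryo, and 5 lists for liver minus embryo. The fits for the average and for liver minus embryo included the E8.5 arrays, where the covariate coincides with genotype. At an adjusted p of 0.10 the E9.5 count was 15.

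With an estimated correlation 0 lists passed at E8.5, E9.5, E11.5 and E12.5, for the average and for liver minus embryo. With fry 1 list passed at E8.5 and 0 in each of the other 5 comparisons.

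Without stage E8.5 the average had 1 target ID and 10 lists, without E9.5 2 lists, without E11.5 3 lists, and without E12.5 5 target IDs.

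With each array left out in turn, the counts ranged from 2 to 3 at E8.5, 0 to 54 at E9.5, 0 to 0 at E11.5 and at E12.5, 0 to 51 for the average and 0 to 68 for liver minus embryo. The lists ranged from 2 to 7 at E8.5, 5 to 10 at E9.5, 5 to 8 at E11.5, 1 to 7 at E12.5, 4 to 9 for the average and 1 to 8 for liver minus embryo. Cirh1a ranged from -1.04 to -0.88 at E8.5, -0.91 to -0.79 at E9.5, -1.01 to -0.82 at E12.5 and -0.94 to -0.88 for the average. The correlations ranged from 0.0375 to 0.287 for E8.5 and E9.5, -0.0196 to 0.125 for E8.5 and E11.5, -0.0372 to 0.0363 for E8.5 and E12.5, 0.0757 to 0.187 for E9.5 and E11.5, -0.10 to 0.0154 for E9.5 and E12.5, and -0.0106 to 0.05 for E11.5 and E12.5.

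Planned and not run, because the signal columns match no sample label, were neqc, normexp, no background correction, cyclic loess and median centring after neqc, the detection filters, and a slide block. The tests of E9.5 against E8.5 and of E12.5 against E11.5, with their alternatives, were not run because the stages were normalized apart.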

Other observations

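The test of the E9.5 count at unadjusted p under 0.05 was chosen after the result was seen; the other tests of this part were set before their results were seen.

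Loss of about 50% of the Cirh1a transcript went along with no call of the SSU processome, cytosolic ribosomal protein or RNA polymerase I list at E8.5, E9.5 or E12.5, the stages with a Cirh1a value. Adjusted over the list alone, 1 member besides Cirh1a passed, the ribosomal protein gene Rps4l at E9.5 (0.28, SE 0.0548). Of 60 SSU processome target IDs on the array, only 24 were tested at E8.5 and 25 at E12.5. Its members Nop58 and Nol6 were among the abundant transcripts that read at background at E8.5. Large subunit biogenesis was called higher at E12.5 and on average, by medians of 0.06 and 0.02. Both calls were lost with an estimated correlation (adjusted p = 0.862 and 0.525) and without single arrays (adjusted p up to 0.575 and 0.136, both without E12.5 heterozygote replicate 2). Of the p53 targets, Ccng1 had 0.42, Phlda3 0.26 and Notch1 -0.39 at E9.5, where the list did not pass (adjusted p = 0.0881, and 0.852 with an estimated correlation). The exonuclease Aen had 0.70, Phlda3 0.53 and Ccng1 0.48 at E8.5, where the list had an adjusted p of 0.495. In liver minus embryo Ccng1 had -0.43 (SE 0.130, adjusted p = 0.693).

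Ciapin1, which takes part in cytosolic iron-sulfur cluster assembly, was higher in the heterozygotes at each of the 4 stages without passing the threshold. The same direction at all 4 stages was a condition of naming it. Cholesterol synthesis was the list called lower at 2 stages of different tissue, E8.5 embryo and E11.5 liver, with an adjusted p of 0.852 at both with an estimated correlation and of 0.0843 at E11.5 without heterozygote replicate 3. At E9.5 its median was 0.03, with 17 of 28 members positive (camera adjusted p = 0.431), and it was not called at E12.5. Its average call depended on E8.5, where sex and genotype coincide. Among the genes of highest level on the hepatocyte list most were higher at E9.5. Apoa1 had 1.29, Apom 1.11, Ttr 0.96, Apoa2 0.89 and Afp 0.77, while Dlk1 had -0.04 and Mt1 -0.03. Of the visceral endoderm, placental and decidual list, Slc13a4 had 0.85, Rhox5 0.74 and Plac8 0.09. Ttr, Apoa1 and Afp also read at 13.64, 12.59 and 9.57 in the E8.5 embryos. Whole embryos do not show which tissue carried these transcripts.

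All 10 splits of the 6 arrays of a stage are too few for a share under 0.05. The real split gave 3 target IDs at E8.5 (1 of 10 splits reached it, highest other 0) and 1 at E9.5 (1 of 10, highest other 0). For the E9.5 count at unadjusted p under 0.05 it gave 1742 (1 of 10, highest other 908). It gave 0 at E11.5 (highest other 5), 0 at E12.5 (highest other 0) and 0 for the average effect (highest other 19). Every split reaches a count of 0, so the shares of 10 of 10, 10 of 10 and 100 of 100 say nothing about chance. The 19 may reflect a structure of the samples, which was not tested.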
